A study of Acorus calamus with 8 samples.

How the data were processed

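RNA was measured in 8 libraries of sweet flag (Acorus calamus) explants grown on Murashige and Skoog medium that held the auxins 2,4-D (2 mg/l) and NAA (0.5 mg/l), per the labels. The libraries cover leaf and rhizome tissue taken from cut and from uncut explants at 4 days and at a month, which the labels count from the cutting for uncut explants as well, with 1 library for each combination and no replicates. Cut leaf stands here for leaf tissue of cut explants, and likewise for the other groups. Per the labels, RNA was either selected by oligo dT or depleted of ribosomal RNA; which was done for each library is not given in the sources used here.

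Per the file headers, each deposited table holds an expected count, an FPKM value, a feature length in bases and annotation text for assembled features. The authors mapped reads to their assembled features with Bowtie2 and obtained the expected counts and FPKM with RSEM, per the submitters' processing notes, which give no versions. A feature missing from a table was taken as 0 counts. The tables name 24636 features in any library, 7067 of them in all 8, and 15697 carry a description. Expected counts were rounded to whole numbers before every test. Contigs of 1 cluster and close paralogues share reads, so their values are not independent.

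Features were put into 3 classes from the deposited annotation: 44 ribosomal RNA features, 235 organelle features and 24357 others, called nuclear here. Library totals run from 6876377 to 12541185 counts. Nuclear features hold from 120332 counts (uncut rhizome at 4 days) to 1695523 (uncut leaf at a month). The largest of them, Unigene19161, has no description, so its class is uncertain; without it the lowest value is 68710. The nuclear shares are given with exact Clopper-Pearson 95% intervals, which, like the intervals of ratios of counts, cover counting error only.

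CPM stands for counts scaled to a common library size. The tests used edgeR 4.0.16 in R 4.3.3: filterByExpr with the design, TMM scaling, robust dispersion and quasi-likelihood F tests. Each factor (tissue, cutting, time) was tested over 4 matched pairs with a block for the other 2 factors, leaving 3 residual degrees of freedom. A fit with separate cutting effects at each level of tissue or of time, leaving 2, gave the effects within each level and their difference. Adjusted p-values are Benjamini-Hochberg over the 11682 features tested, with a threshold of 0.05. Errors are standard errors of the log2 fold change, taken as its size over the square root of F. With 1 library per combination the p-values measure only the spread between these 8 libraries. The tests within a time point rest on 2 pairs each, and the spread between tissues serves as their error. The fit draws each feature's spread toward that of all features. Very small p-values there therefore cannot come from a feature's own 2 pairs and are not evidence from replicates.

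The 4 cut against uncut pairs were also read one by one with a size rule and no p-value. A feature passed with at least 50 counts in the higher library and at least a 4-fold change after TMM scaling, the lower library being counted as at least 3. Where a whole group held 0 counts, the fold change is given as a lower bound against a floor of 3 counts over the group. Where it held 1 to 3, the ratio is given with its counting interval. Ratios over several libraries pool their counts, so they do not keep the pairing. Intervals of medians are 95% bootstrap intervals over features, computed exactly for an odd number of features, a choice made after seeing the data. Medians of log2 ratios per list were set against 10000 random lists matched on mean expression.

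Lists of features were written from the descriptions before any list was tested; 34 of 35 were tested, with at least 5 members each. The tests were camera in limma 3.58.1 with a preset correlation of 0.01, camera with an estimated correlation and fry, on log2 CPM with a prior count of 2. The list of proteins named after other organisms was corrected after descriptions had been seen, before any list was tested.

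A feature was named when it was past the threshold, held a mean of at least 10 CPM over the 8 libraries, moved alike in every pair and carried a description. Up to 10 per direction were named for a factor, 5 per single pair and 3 per list, the last by the smallest p, or in a single pair by the largest ratio, without the limits on CPM and direction. Descriptions come from the Nr annotation unless SwissProt is stated. The rule that strips endings from descriptions was corrected after results had been seen, which changed which like-named features were merged. The 3 features named for cutting within rhizome, 1 of which is also the single cutting call, were chosen after their values were seen. One feature that the rule named is not reported here.

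The groups, the comparisons and a first set of alternatives were fixed before the data were examined: DESeq2 1.42.0 size factors, the DESeq2 Wald test, no count filter or a stricter one, an additive model, leaving out each pair, and limma-trend on log2 FPKM with 1 or 0.1 added. The others were chosen after seeing the data: leaving out the ribosomal RNA and organelle features, an offset for each library's trend on feature length (natural spline, 3 interior knots), subtraction of a constant rate of counts per kilobase (the 10th percentile of nuclear features of at least 2000 bases), summed contigs of each cluster, and time without the 4 cut libraries. So were the ratios with each library left out in turn, all alternatives within a tissue or time point, list tests and named features within a time point, random lists also matched on length, list medians under each scaling and the set of 43 retrotransposon features.

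The factor tests and the test within 4 days were tested on simulated data with 200 changed features, 50 at each size. The changed features were drawn from those with a mean of at least 10 CPM and at least 10 counts. Apart from the simulated changes, each feature had the same mean CPM in all libraries. The recovery therefore does not describe less abundant features or data in which the other factors also act. The tissue test recovered 8% of 2-fold, 56% of 4-fold and 98% of 8-fold changes, with 13 false calls of 143. The cutting test recovered 0%, 36% and 90% (14 false of 127), the time test 0%, 24% and 80% (5 of 105), and the test within 4 days 0%, 32% and 84% (4 of 112). Files were read and figures drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. No sequences were used, so base composition was not analysed here.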

Results

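Ribosomal RNA features hold most of the counts in all 8 libraries, from 74.98% in uncut leaf at a month to 97.9% in uncut rhizome at 4 days. Organelle features hold 9.92% to 12.7% of the counts in leaf and 0.380% to 2.18% in rhizome. Nuclear features make up the rest: 14.67% [14.65, 14.69] in uncut leaf at a month, 8.390% [8.373, 8.407] in cut rhizome at 4 days and 1.75% [1.74, 1.76] in uncut rhizome at 4 days. In that last library only 1560 nuclear features reach 10 counts, against 8780 in cut rhizome at 4 days and 11527 in uncut leaf at a month. Unigene19161, an undescribed feature of 310 bases, is the largest nuclear feature and holds 0.751% to 2.66% of a library. Its class is uncertain, and without it the nuclear counts of uncut rhizome at 4 days drop from 120332 to 68710 and those of cut rhizome at a month from 467832 to 269572. The 43 retrotransposon features hold 883 and 903 CPM in cut leaf and cut rhizome at 4 days. In uncut leaf and uncut rhizome at 4 days they hold 19.2 and 6.43. At a month they hold 28.5 in cut and 156 in uncut leaf, and 178 in cut and 31.6 in uncut rhizome. These CPM are over all counts, ribosomal RNA included and without TMM scaling, so they also follow the ribosomal RNA share. Of nuclear counts, these features hold 1.13% and 1.08% in cut leaf and cut rhizome at 4 days. The uncut values are 0.0191% and 0.0367%. At a month the shares are 0.0357% in cut and 0.107% in uncut leaf, and 0.413% in cut and 0.0738% in uncut rhizome.

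**Figure D1:**
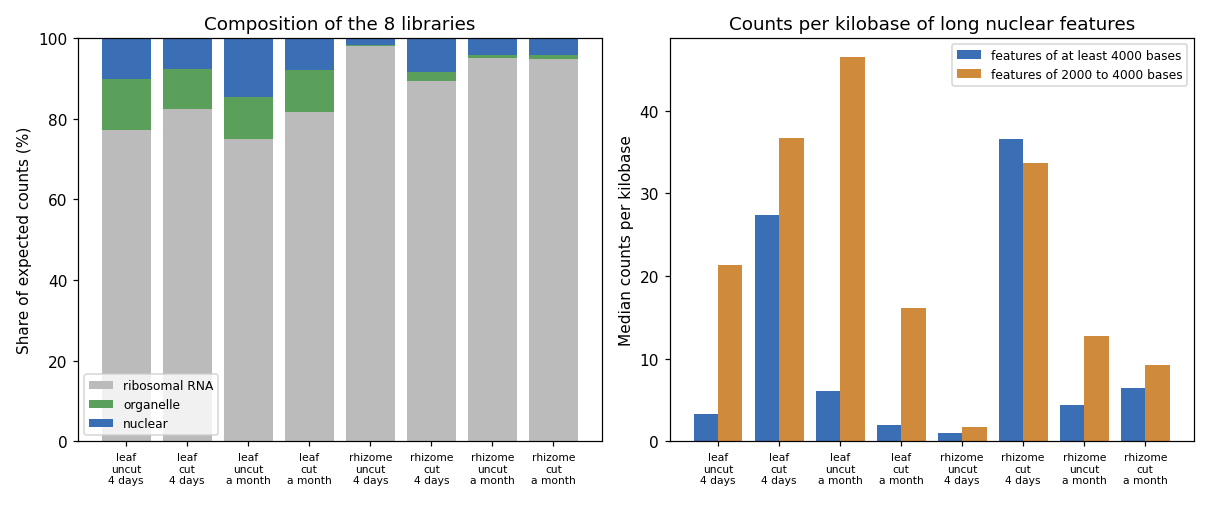
Stacked bars give the percent of counts in ribosomal RNA, organelle and nuclear features in each of the 8 libraries, and the second panel gives the median counts per kilobase over 114 nuclear features of at least 4 kb and over 1161 of 2 to 4 kb. Over the longer ones the medians are 27.4 (leaf) and 36.6 (rhizome) in the cut libraries at 4 days and 0.948 to 6.48 in the other 6.

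The tissue question is which features differ between rhizome and leaf over the 4 combinations of cutting and time point. Several photosynthesis genes were far lower in rhizome: CSP41b (Unigene5092), a chloroplast RNA-binding protein, fell by 6.40 ± 0.76 on the log2 scale (adjusted p = 0.000195), and CP12-1 (Unigene9391), which holds Calvin cycle enzymes inactive in the dark, fell by 5.80 ± 0.56 (0.000113). Rubisco activase (CL1693.Contig1) fell by 5.47 ± 0.65 (0.000212), the light-harvesting protein CAB8 (CL1624.Contig2) by 5.44 ± 0.55 (0.000113) and the photorespiratory serine-glyoxylate aminotransferase (Unigene7202) by 5.04 ± 0.55. Among those higher in rhizome were a lipid-transfer protein (CL80.Contig2, log2 8.01 ± 0.86, 0.000135; 1084 against 5 counts, of which 1001 lie in cut rhizome at 4 days), pectate lyase 5 (Unigene8561, 5.46 ± 0.66, 0.000172), which breaks pectin, and a lectin (CL1454.Contig2, 5.07 ± 0.54, 0.000123). Each of these moved alike in all 4 pairs, and the calls held without any 1 pair. Some values moved by over 1.5-fold: without the cut 4-day pair CSP41b fell by 10.75 (its pooled ratio of 37.3 is 123 without cut rhizome at 4 days) and the aminotransferase by 5.66, while the lipid-transfer protein was at 6.70 and pectate lyase at 6.48. Without the uncut 4-day pair these last were at 11 and 4.62, and without the uncut month pair Rubisco activase fell by 4.72. An extensin-domain feature (Unigene9808) had 339 counts in rhizome and 3 in leaf, a 258-fold ratio [87.5, 1260], or 108-fold without uncut rhizome at 4 days, and did not reach the count filter without either 4-day pair.

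By edgeR, 1051 of 11682 features passed, 242 higher and 809 lower in rhizome, 984 of them alike in all 4 pairs; 2786 had an unadjusted p under 0.05. Without the uncut 4-day pair 444 passed, without the uncut month pair 601 and without the cut month pair 630. Of the 93 features named for tissue, 56 stayed past the threshold without the uncut 4-day pair. The test on FPKM gave 79 higher and 2503 lower with 1 added and 62 and 2208 with 0.1 added, the subtraction gave 637 features, no count filter 1608, and the length offset 590 higher and 693 lower.

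Hormone genes moved in more than 1 direction between the tissues. Higher in rhizome were GH3.2 (Unigene6256, 3.55 ± 0.70), which ties auxin to amino acids and did not reach the count filter without the uncut month pair, cytokinin dehydrogenase 5 (Unigene6200, 5.11 ± 0.76, adjusted p = 0.00123, or 6.15 without the cut month pair), which breaks down cytokinin, and the response regulator ARR9 (CL2354.Contig2, 2.28 ± 0.52), which was at 2.88 without the cut 4-day pair and no longer passed without the uncut 4-day pair (1.95). The gibberellin-responsive GAST1 (Unigene785) was higher by 7.20 ± 0.84 (adjusted p = 0.000156), with 93 counts in rhizome and 3 in leaf, a 70.8-fold ratio [23.5, 349]. Uncut rhizome at 4 days holds 77 of these counts, and the ratio is 13.1 without it and 121 without cut rhizome at 4 days; it reached the count filter only without the cut month pair (7.25). Lower were the abscisic acid synthesis genes NCED (Unigene10574), which fell by 4.06 ± 0.71, and zeaxanthin epoxidase (Unigene1460), which fell by 2.91 ± 0.53. Without either month pair NCED did not reach the count filter, and its pooled ratio of 14.7 is 7.68 without cut rhizome at 4 days and 119 without cut rhizome at a month. A homeobox feature (Unigene4163, knotted-1-like 10 by SwissProt) was higher by 4.35 ± 0.67 (adjusted p = 0.000896), while HOX6 (Unigene2067) had 2 counts in rhizome and 336 in leaf, a 73.6-fold ratio [20.2, 610], or 29.6-fold without uncut leaf at a month. All of these moved alike in the 4 pairs.

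Of 34 lists, 11 passed camera for tissue. Photosystem members were lower in 54 of 73 (64 lower and 1 higher adjusted over the list alone), with a median log2 change of -3.53 (adjusted p = 8.16e-30), or -3.33 with empty groups at their bound. Calvin cycle members were lower in 17 of 22 (19 lower and 1 higher adjusted over the list alone), with a median of -4.09 (7.54e-14). Chlorophyll synthesis, with 7 of 15 lower (9 adjusted over the list alone) and a median of -2.07 (1.21e-05), includes the magnesium chelatase subunit ChlH (Unigene1580), which fell by 3.06 ± 0.43. O-methyltransferases and terpene synthases had 7 of 31 lower (10 adjusted over the list alone) and a median of -1.36 (0.000159), among them propenylphenol synthase 1 (Unigene10471), which fell by 2.59 ± 0.50, and terpene synthase 10 (Unigene3932), which fell by 3.62 ± 0.62, or by 4.33 without the cut month pair. Wall loosening had 11 of 61 higher and 2 lower (17 and 6 adjusted over the list alone, 0.000514), with a median of 0.83 that turns to -0.13 and -0.31 on FPKM with 1 and 0.1 added. None passed camera once the correlation was estimated: adjusted p = 0.592 with an estimated correlation for photosystems, 0.386 for the Calvin cycle and chlorophyll synthesis, and 0.716 for the other 2. By fry, chlorophyll synthesis (adjusted p = 0.0035), the Calvin cycle (0.00866) and photosystems (0.0248) passed. O-methyltransferases and terpene synthases (0.0821) and wall loosening (0.363) did not. Peroxidases, which did not pass, had 4 higher and 5 lower of 51. Storage proteins and lectins, the list planned as a check of rhizome identity, did not pass either (camera adjusted p = 0.39). That list had 4 of 44 members higher and 1 lower in rhizome, with a median of 0.064.

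The time question is which features differ between a month and 4 days after the cutting, in cut and uncut explants alike. Several genes of dryness and cold responses were far higher at a month: the dehydrins Rab18 (CL1434.Contig2, log2 7.87 ± 1.10, adjusted p = 0.00164) and COR410 (Unigene4074, 7.38 ± 0.84, 0.000469), and LEA2 (CL837.Contig4, 7.18 ± 0.81, 0.000438), proteins that build up as cells lose water. So were the arabinogalactan protein AGP9 (CL2290.Contig1, 8.96 ± 0.85, 0.000246), the ethylene response factor ERF054 (Unigene7179, 7.87 ± 0.73, 0.000246) and the metal-binding HIPP22 (Unigene7247, 7.75 ± 0.74). Pectate lyase 5 (Unigene8561) fell by 5.99 ± 0.82 (adjusted p = 0.000985), a light-harvesting protein (Unigene3503) by 2.98 ± 0.63 (0.00987), and sucrose synthase (CL1148.Contig2), which splits sucrose in sink tissue, by 2.38 ± 0.67 (0.0471). Each moved alike in all 4 pairs. Without the cut leaf pair Rab18 was at 6.53, COR410 at 6.51, LEA2 at 6.24, AGP9 at 8.05 and HIPP22 at 7.05; without the uncut leaf pair they were at 9.33, 8.02, 7.78, 10.6 and 8.48, and without the cut rhizome pair Rab18 was at 7.0 and COR410 at 8.03. The pooled ratio of Rab18, 236, is 78.4 without cut leaf at a month and 484 without uncut leaf at 4 days. Pectate lyase 5 fell by 7.53 without the cut and by 4.94 without the uncut rhizome pair. The light-harvesting call ended without the uncut leaf pair (-2.21), and that of sucrose synthase without the uncut leaf (-1.80), cut leaf (-1.98) or cut rhizome pair (-2.65), the value being -3.18 without the uncut rhizome pair.

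By edgeR, 1023 features passed, 912 higher and 111 lower at a month (2231 with unadjusted p under 0.05), 975 of them alike in all 4 pairs. Without the uncut leaf pair 589 passed and without the cut rhizome pair 612; of the 93 features named for time, 63 stayed past the threshold without the uncut leaf pair. The length offset gave 695 higher and 396 lower, the subtraction 499 features and the 4 uncut libraries alone 425 (349 higher and 76 lower).

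**Figure D2:**
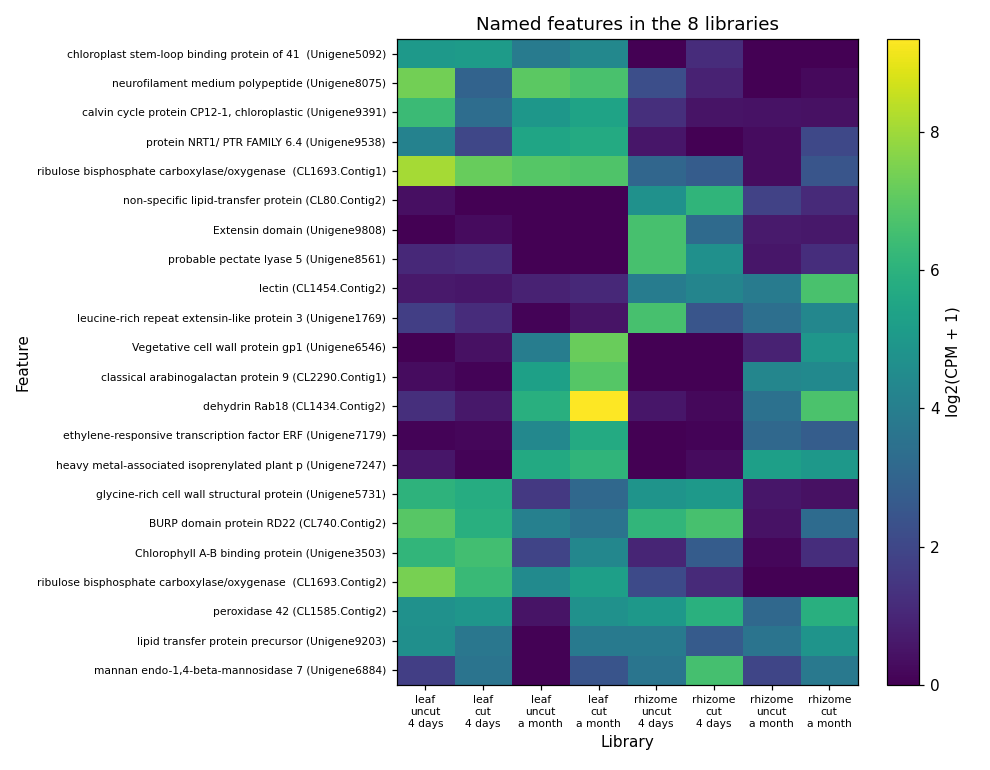
The heat map shows log2 of CPM plus 1 for up to 5 named features of each kind (lower and higher in rhizome, higher and lower at a month, higher in cut explants at a month), 1 line per feature and 1 column per library. Rab18 (CL1434.Contig2, log2 7.87 for time) stands higher in the 4 month libraries than in those at 4 days, and CSP41b (Unigene5092, -6.40 for tissue) higher in the 4 leaf libraries than in rhizome.

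Some abscisic acid genes were among those higher at a month. NCED (Unigene10574), which makes the abscisic acid precursor, was higher by 5.96 ± 0.89 (adjusted p = 0.00157), the bZIP factors ABI5-like 5 (Unigene5000) by 3.46 ± 0.53 and TRAB1 (CL1459.Contig2) by 4.19 ± 0.75. A gibberellin 2-oxidase (CL310.Contig1), of the enzymes that inactivate gibberellin, was higher by 4.41 ± 0.73, and so were the cell cycle inhibitors SMR4 (Unigene8366, 6.47 ± 0.71) and SMR13 (CL2588.Contig2, 5.33 ± 0.62). Expansin-A8 (CL715.Contig3), which loosens walls, fell by 5.02 ± 0.69, the auxin-responsive IAA30 (CL718.Contig1) by 3.18 ± 0.54 and ARR9 (CL2354.Contig2) by 2.85 ± 0.58. Beta-amylase 1 (CL2263.Contig1), which breaks down starch, rose by 5.72 ± 0.80, and WRKY40 (CL131.Contig1), a stress and defence regulator, by 7.16 ± 0.78 (433 against 2 counts, 196-fold [54.0, 1620]). These moved alike in all 4 pairs. Without the uncut leaf pair SMR4 was at 7.44 and the ARR9 call ended (-2.53). Expansin-A8 fell by 5.76 without the cut leaf pair, and its pooled ratio of 48.9 is 22.8 without cut rhizome at 4 days. Beta-amylase 1 was at 5.0 without the cut rhizome pair. NCED and TRAB1 did not reach the count filter without either leaf pair.

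For time, 16 lists passed camera. Late embryogenesis and dehydrins had 11 of 15 higher (11 adjusted over the list alone), with a median log2 change of 6.25 (adjusted p = 1.6e-06), or 4.66 with empty groups at their bound. Ethylene genes had 25 of 77 higher (26 adjusted over the list alone) and a median of 0.43 (0.000249). Heat shock genes had 16 of 68 higher (22 adjusted over the list alone) and a median of 1.12 (0.000249), jasmonate genes 11 of 31 (11 adjusted over the list alone, median 0.88, 0.000377) and abscisic acid genes 7 of 15 (7 adjusted over the list alone, median 2.11, 0.00325). Photosystem genes had 9 of 73 lower and 1 higher (13 and 1 adjusted over the list alone) and a median of -1.14 (1.11e-09). Wall loosening had 12 of 61 lower and 7 higher (17 and 8 adjusted over the list alone) and a median of -0.79 (0.00352). The cell cycle list had a median of -0.43 (0.0245) that turns to 0.13 after the subtraction, yet its 4 members past the threshold (3 adjusted over the list alone) were higher and include the inhibitors SMR4 and SMR13. None passed camera once the correlation was estimated: adjusted p = 0.441 with an estimated correlation for heat shock, 0.663 for the cell cycle and 0.513 for the other lists given here. By fry, heat shock passed (adjusted p = 0.0167), as did dehydrins, ethylene and abscisic acid genes (0.049 each). Jasmonate (0.0578), wall loosening (0.341), the cell cycle (0.862) and photosystems did not.

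The cutting question is which features differ between cut and uncut explants over both tissues and time points. One undescribed feature of 253 bases with a chloroplast match, Unigene19159, passed: it fell by 7.70 ± 1.0 (adjusted p = 0.0125), from 507 counts in uncut to 2 in cut explants, a 208-fold ratio [57.2, 1720], or 88.2 without uncut rhizome and 355 without uncut leaf at a month. The call ended without the leaf (-7.66) or the rhizome 4-day pair (-6.63); without the leaf month pair the value was -10.55 and without the rhizome month pair -6.91. Some starch genes lay higher after cutting without passing: granule-bound starch synthase 1 (Unigene8022) at 1.53 ± 0.48 (adjusted p = 0.392, 4 of 4 pairs; a pooled ratio of 3.43, or 2.13 without uncut leaf at a month) and the large subunit of ADP-glucose pyrophosphorylase (Unigene8196) at 2.46 ± 0.78 (0.392; 6.16, or 11.4 without uncut rhizome at a month).

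By edgeR 1 feature passed, with 967 at an unadjusted p under 0.05; DESeq2 gave 77 (60 higher) and limma on FPKM 3 with 1 added and 4 with 0.1 added. Leaving out the leaf month pair gave 274 (224 higher and 50 lower), the rhizome month pair 10 and either 4-day pair 0 (363 without the leaf and 592 without the rhizome pair at an unadjusted p under 0.05). No count filter gave 113 (95 higher), the length offset 12 and summed contigs 3, and edgeR gave 0 in the additive model, after the subtraction and without ribosomal RNA and organelle features (978, 473 and 919 at an unadjusted p under 0.05). Of the lists, 5 passed camera with no member past the threshold. Starch synthesis had a median of 0.65 (adjusted p = 0.0174, 3 higher adjusted over the list alone), storage proteins and lectins one of -0.39 (0.0174, 0 adjusted over the list alone) and proteins named after other organisms one of 1.84 (0.0255, 1 higher adjusted over the list alone). After the subtraction these medians are 0.174, -1.265 and 0.461, and on FPKM with 1 added 0.231, -0.408 and 0.666. For each of the 5, adjusted p = 0.961 with an estimated correlation. The last list holds mainly plant proteins named for virus multiplication and retrotransposon polyproteins.

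Within rhizome, 3 features passed, all lower in cut explants in the 2 pairs together (455 with unadjusted p under 0.05; 14 by DESeq2, 10 of them higher). The organic cation and carnitine transporter OCT4 (Unigene10532) fell by 5.46 ± 0.78 (adjusted p = 0.00491). It had 83 counts in cut and 5463 in uncut rhizome, a pooled 133-fold ratio [107, 167]. That ratio pools libraries of unlike depth and lies above the ratio of the month pair alone, given below. Uncut rhizome at a month holds 5408 of these counts, and the pooled ratio is 6.45 without that library and 718 without cut rhizome at a month. CL2369.Contig2, undescribed, had 0 and 2741 counts (at least 1850-fold lower, adjusted p = 0.00167, or at least 32.5-fold without uncut rhizome at a month), and Unigene19159 had 0 and 379 (at least 256-fold lower, 0.0022, or at least 73.0-fold without cut rhizome at 4 days). Within leaf, edgeR and DESeq2 each gave 0, with 409 at an unadjusted p under 0.05 by edgeR. The test for a difference between rhizome and leaf gave 0 by edgeR, with 199 at an unadjusted p under 0.05, and 1 by DESeq2; OCT4 therefore cannot be said to respond in rhizome alone. Without the leaf month pair the counts were 40 in leaf and 30 in rhizome (33 and 23 of them higher), without the leaf 4-day pair 6 and 26, and rhizome gave 0 without its 4-day or its month pair (297 and 1186 at an unadjusted p under 0.05). The stricter count filter gave 0 in rhizome (311 at an unadjusted p under 0.05), the length offset 8 in leaf and 14 in rhizome, and the subtraction 3 and 35 (3 and 27 higher).

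At 4 days, the question is what differs between cut and uncut explants over the leaf and the rhizome pair. Among described features with a mean of at least 10 CPM over the 8 libraries, the largest rises were in retrotransposon features: a reverse transcriptase (CL30.Contig4, log2 6.79 ± 0.77, adjusted p = 5.05e-15) and a gag-pol polyprotein (Unigene2355, 6.78 ± 0.77, 5.48e-15). Elongation factor 1-alpha (CL100.Contig12), which brings transfer RNA to the ribosome, rose by 3.86 ± 0.68 (2.25e-06), the large subunit of ADP-glucose pyrophosphorylase (Unigene8196), which begins starch synthesis, by 4.90 ± 1.01 (0.000122), and the auxin response factors ARF8 (CL668.Contig2) by 3.99 ± 0.86 (0.000283) and ARF6 (CL1096.Contig2) by 2.66 ± 0.75 (0.0101). Lower in cut explants were an aquaporin (CL2613.Contig6), which fell by 5.31 ± 0.77 (2.32e-09), the 17.3 kDa heat shock protein (Unigene9097), which fell by 3.81 ± 0.65 (1.42e-06), and a rubisco small chain (Unigene10191), which fell by 3.47 ± 0.64 (1.11e-05). All of these moved alike in both pairs. Their small p-values rest on spread shared across features, not on these 2 pairs alone. Without the leaf 4-day pair the reverse transcriptase (6.96), the gag-pol feature (6.01), the pyrophosphorylase (8.98) and ARF8 (3.02) no longer passed. Without the rhizome 4-day pair the gag-pol feature (7.40), the reverse transcriptase (6.79) and ARF6 (1.87) no longer passed. Elongation factor 1-alpha was at 6.65 and 2.81 without the leaf and the rhizome 4-day pair, the aquaporin at -4.28 and -9.53 and the rubisco small chain at -5.12 and -2.39. ARF6, at 9.65 without the leaf 4-day pair, also no longer passed without either month pair (2.48 and 2.77).

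Further named genes passed at 4 days. Higher were the kinesin KIN-UB (Unigene9285, 3.60 ± 0.87, adjusted p = 0.0017), the cellulose synthase CESA8 (Unigene3676, 2.12 ± 0.62, 0.0127) and fructokinase-2 (CL233.Contig1, 2.26 ± 0.67, 0.0156). Sucrose synthase (CL1148.Contig2) rose by 2.17 ± 0.58 (0.0055), a rise that turns to -0.07 with the length offset. Lower were SAUR32 (Unigene8057), which fell by 2.96 ± 0.70 (0.00122), and NAC100 (CL2382.Contig1), which fell by 3.83 ± 1.02 (0.00546). Each moved alike in the leaf and the rhizome pair, but each call ended without at least 1 pair. Without the leaf 4-day pair KIN-UB (3.77), CESA8 (1.90), fructokinase-2 (2.63) and sucrose synthase (1.71) no longer passed, SAUR32 was at -3.96 and NAC100 did not reach the count filter, nor did it without the leaf month pair. Without the rhizome 4-day pair fructokinase-2 (2.11), sucrose synthase (2.75) and SAUR32 (-2.08) no longer passed. Without the leaf month pair KIN-UB (3.34), CESA8 (1.88), fructokinase-2 (2.02) and sucrose synthase (1.93) no longer passed, and without the rhizome month pair these (3.63, 2.14, 2.29 and 2.19) and NAC100 (-3.80) did not.

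By edgeR, 816 features passed at 4 days, 542 higher and 274 lower (2257 with unadjusted p under 0.05), 795 of them alike in both pairs; DESeq2 gave 428. Leaving out the leaf 4-day pair gave 169 (84 higher and 85 lower), the rhizome 4-day pair 405, the leaf month pair 300 and the rhizome month pair 308. Of the 68 features named at 4 days, 24 stayed past the threshold without the leaf and 28 without the rhizome 4-day pair. With the length offset 36 of them stayed past it and after the subtraction 25. The stricter count filter gave 300, the length offset 257 higher and 183 lower, and the subtraction 44 higher and 132 lower. The features called higher have a median length of 2270.5 bases, those called lower 828 and all tested 1126.

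**Figure D3:**
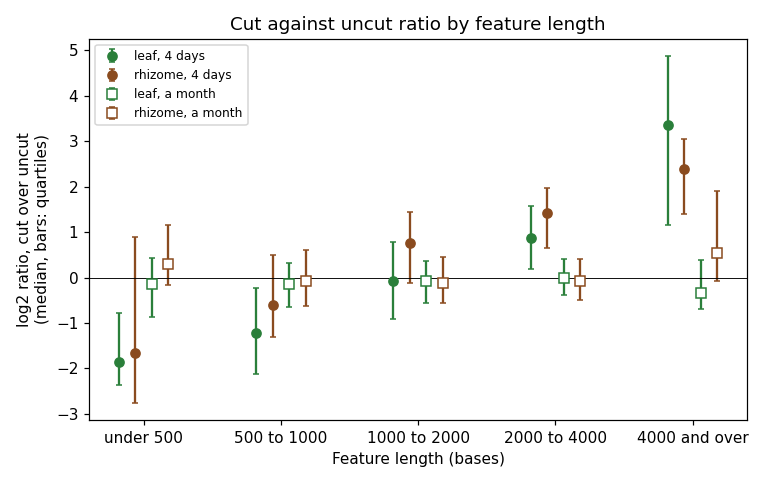
Points give the median log2 ratio of cut to uncut in bins of feature length, with bars for the quartiles, for the 4 pairs. At 4 days the medians climb with length to 3.36 in leaf and 2.39 in rhizome for features of at least 4 kb, against -0.33 and 0.54 at a month.

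Of the lists, 10 passed camera at 4 days. Starch synthesis had 2 of 19 higher (4 adjusted over the list alone), with a median log2 change of 1.41 (adjusted p = 0.0172, and 0.51 with the length trend removed). Storage proteins and lectins had 3 of 44 lower (4 adjusted over the list alone), with a median of -1.03 (0.00373, and 0.0558 with the length trend removed). Cell cycle genes had 11 of 73 higher (13 adjusted over the list alone), with a median of 0.89 that turns to -0.26 after the subtraction (0.0112, and 0.0805 with the length trend removed). Proteins named after other organisms had 7 of 20 higher (11 adjusted over the list alone), with a median of 3.33 (0.0055, and 0.000243 with the length trend removed). For each of these, adjusted p = 0.825 with an estimated correlation. The medians depend on the scaling. With the length offset and after the subtraction they are 0.721 and 0.589 for starch synthesis and -0.535 and -3.382 for storage proteins and lectins. For the cell cycle they are 0.581 and -0.263, and for proteins named after other organisms 3.765 and 2.433.

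At a month, few features differed between cut and uncut explants over the leaf and the rhizome pair. Higher were peroxidase 42 (CL1585.Contig2, log2 4.32 ± 0.68, adjusted p = 1.07e-06), a lipid-transfer protein (Unigene9203, 3.73 ± 0.81, 0.00642), the wall enzyme mannan endo-beta-mannosidase 7 (Unigene6884, 3.67 ± 0.70, 0.000216), the dehydrin Rab18 (CL1434.Contig2, 3.40 ± 0.60, 2.54e-05), a defensin (CL1025.Contig2, 2.96 ± 0.66, 0.00642) and tubulin beta-1 (CL2623.Contig4, 2.63 ± 0.63, 0.0195). LEA1 (CL837.Contig1) rose by 6.91 ± 1.47 (0.0028) on 61 against 1 counts, a 144-fold ratio [24.9, 5790], or 10.4 without uncut leaf at a month. Without the leaf month pair none of the other calls held (peroxidase 42 at 2.89, the lipid-transfer protein at 1.27, the mannosidase at 2.16, Rab18 at 3.29, the defensin at 1.14 and the tubulin at 1.46), and LEA1 did not reach the count filter without either month pair. Without the rhizome month pair they were at 5.92, 8.21, 6.63, 3.46, 4.74 and 3.94, with Rab18 and the tubulin no longer past the threshold. Of the 10 features named at a month, 3 stayed past it without the leaf and 5 without the rhizome 4-day pair. All moved alike in both pairs, and no described feature called lower met the rule for naming.

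By edgeR, 34 features passed at a month, 28 higher and 6 lower (539 with unadjusted p under 0.05); 31 moved alike in both pairs and DESeq2 gave 12. The stricter count filter and the subtraction gave 0 (327 and 223 at an unadjusted p under 0.05) and the length offset 19. Without the leaf month pair 5 passed, 0 higher and 5 lower, without the leaf 4-day pair 7 and without the rhizome month pair 20. Of the lists, 9 passed camera: late embryogenesis and dehydrins had 2 of 15 higher (3 adjusted over the list alone) and a median of 1.04 (adjusted p = 1.27e-05), and photosystems 1 of 73 higher and a median of 0.82 (4.64e-06). DNA replication had a median of -0.97 (0.0214), or -0.54 with empty groups at their bound. For these 3, adjusted p = 0.854 with an estimated correlation.

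The test for a different response to cutting at a month and at 4 days gave 229 features, 119 with a higher and 110 with a lower value at a month (1392 with unadjusted p under 0.05; 102 by DESeq2). GAST1 (Unigene785) differed by 6.98, Rab18 (CL1434.Contig2) by 4.87, peroxidase 42 (CL1585.Contig2) by 3.74 and the gag-pol feature (Unigene2355) by -5.94. GAST1 holds 77 counts in uncut rhizome at 4 days but 2 in uncut and 4 in cut rhizome at a month, and did not reach the count filter without either rhizome pair. Without the leaf month pair none of these calls held, and the gag-pol value was -3.61 and that of peroxidase 42 2.55. The stricter filter gave 18, the length offset 114 and the subtraction 0 (1431 at an unadjusted p under 0.05). Leaving out the leaf month pair gave 9, the rhizome month pair 77 (30 with a higher and 47 with a lower value), the leaf 4-day pair 83 and the rhizome 4-day pair 91.

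Read one pair at a time, with no test, 796 features passed the size rule in leaf at 4 days (453 higher, 343 lower; 293 and 549 on FPKM) and 519 in rhizome (454 and 65; 2193 and 22 on FPKM, and 454 and 390 with a minimum of 10 counts). The minimum is on counts not scaled for depth, and uncut rhizome holds 120332 nuclear counts against 855290 in cut rhizome. The rule therefore favours rises in this pair, and how much of their excess comes from this was not tested. The median log2 ratio of the rhizome features kept is 1.009, but -0.062 with a minimum of 10 counts. With a minimum of 200 it is 1.005 (132 higher, 19 lower). In leaf the gag-pol feature (Unigene2355) went from 12 to 1861 counts, a 167-fold ratio [95.3, 323], while the cold-regulated CORA (Unigene5952) went from 276 to 7 (36.7-fold lower [17.6, 92]). An oxalate-CoA ligase (CL1218.Contig1) went from 287 to 0 (at least 88.9-fold lower). In rhizome GAST1 (Unigene785) went from 77 to 10 (53.6-fold lower [27.6, 116]) and a glycine-rich wall protein (Unigene7236) from 183 to 22 (57.9-fold lower [37.1, 94.6]). NAC factors had a median of -1.04 in leaf, below all but 0.5% of random lists, and of -0.18 in rhizome, below all but 5.4%.

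At a month, 204 features passed in leaf (83 higher, 121 lower; 24 and 936 on FPKM, but 332 and 179 with a minimum of 10 counts and 28 and 21 with one of 200) and 85 in rhizome (65 and 20; 45 and 31 on FPKM). In leaf, peroxidase 42 (CL1585.Contig2) went from 12 to 256 counts (63.1-fold [35.5, 124]), AGP19 (CL403.Contig2) from 14 to 216 (45.6-fold [26.6, 84.9]) and terpene synthase 10 (CL507.Contig3) from 273 to 0 (at least 30.8-fold lower). In rhizome OCT4 (Unigene10532) went from 5408 to 72 (54.8-fold lower [43.4, 70.1]), GATA1 (CL2251.Contig1) from 883 to 8 (80.5-fold lower [40.7, 187]) and the transcription factor ERF061 (Unigene5496) from 137 to 6 (16.7-fold lower).

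Across the 6772 features with at least 50 counts in any of the 8 libraries, the cut to uncut log2 ratios were correlated between pairs. Leaf and rhizome at 4 days correlate with r = 0.587, the month pairs with r = 0.159. Only 2833 features reach 50 counts in the rhizome pair at 4 days, so many ratios there rest on fewer counts or on the floor of 3. Between the time points r is 0.116 in leaf and 0.099 in rhizome. With at least 10 counts the first value is 0.477. Over nuclear features, the ratios at 4 days also rise with feature length (Spearman 0.55 in leaf and 0.48 in rhizome). Those at a month hardly do (0.07 and 0.02). How much of the 0.587 comes from this shared length trend was not tested. Features are not independent replicates, so no p-value is attached.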

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

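The tests of depth for the retrotransposon features, the calls by feature length, the percent of dehydrin features called, the differences between the time points without a pair and all tests with the length offset or the subtraction were chosen after the result was seen; leaving out a pair for time and the splits of the libraries were planned, but keeping to those that part all pairs was not. The features named here were picked out because the effect of cutting differed between a month and 4 days by the interaction test in edgeR, and the value a feature gave is the log2 change on cutting at a month minus that at 4 days. In all, 229 features differed, and 102 by DESeq2. After the subtraction edgeR gave 0, with 1431 at an unadjusted p under 0.05. Of the 42 features named, 14 stayed past the threshold without the leaf 4-day pair, 12 without the rhizome 4-day pair, 2 without the leaf month pair and 19 without the rhizome month pair.

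Of the 229 features, 119 gave positive and 110 negative values. GAST1 (Unigene785) gave 6.98, which rests on uncut rhizome at 4 days: that library holds 77 of its counts, cut rhizome at 4 days 10, and uncut and cut rhizome at a month 2 and 4, and it did not reach the count filter without either rhizome pair. The GRAS factor scarecrow-like 3 (Unigene8805) gave 6.0, and the jasmonate synthesis gene allene oxide synthase 7.11 (Unigene5276) and 4.61 (CL1753.Contig2). ERF4 (Unigene97) gave 3.28. The dehydrin Rab18 (CL1434.Contig2) gave 4.87 and the cold-induced SRC1 (CL354.Contig2) 2.64. Small heat shock proteins gave 3.98 (Unigene9097), 6.41 (CL1067.Contig3) and 5.05 (Unigene242). Peroxidase 42 (CL1585.Contig2) gave 3.74, a lipid-transfer protein (Unigene9203) 4.87 and a defensin (CL1025.Contig2) 4.32.

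The aquaporin CL2613.Contig6 gave 5.53 and the wall enzyme XTH6 (Unigene10551) 3.99. Glycine-rich wall proteins gave 4.11 (CL644.Contig1) and 3.85 (Unigene5971), and a feature named pherophorin-dz1 (Unigene3858; a glycine-rich wall protein by SwissProt) gave 4.28. The sulfated surface glycoprotein CL1562.Contig1 gave 3.94, Unigene1256 (chitin-binding lectin 1 by SwissProt) 3.24, Unigene1487 (vicilin-like by SwissProt) 3.86 and Unigene8075 (a metal-binding isoprenylated protein by SwissProt) 3.52. A rubisco small chain (Unigene10191) gave 4.34, beta-amylase 1 (CL2263.Contig1) 3.15, and the plastid protein TIC214 (CL2222.Contig2) 8.54. Histone H1-I (Unigene4969) gave 3.47 and Unigene1449 (histone H3.3 by SwissProt) 3.51.

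The retrotransposon features gave -6.0 (CL30.Contig4), -5.94 (Unigene2355), -5.73 (CL112.Contig3), -5.14 (CL30.Contig5), -4.45 (CL30.Contig6), -4.50 (CL15.Contig3), -7.40 (CL15.Contig4) and -8.24 (CL15.Contig2). A basic proline-rich protein (CL143.Contig4) gave -4.60 and a leucine-rich repeat extensin-like protein 4 (CL143.Contig3) -4.00. Cellulose synthase CESA2 (Unigene7049) gave -4.32 and a SANT/Myb-domain feature (Unigene2468; cell division cycle 5-like by SwissProt) -3.19. Of organelle features with negative values, ATP synthase CF1 alpha (CL733.Contig1) gave -3.38, orf169 (Unigene3800) -4.97 and an RNA polymerase subunit (Unigene1225) -11.11. The last is a fitted value that depends on the prior count, since the uncut explants at 4 days hold 0 counts of it. The plastid protein TIC214 (CL2222.Contig2), given above, went the other way at 8.54.

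The libraries of cut explants at 4 days held more counts in retrotransposon features. The median log2 change was 5.71 [3.99, 6.39] over the 23 of 43 features that reached the count filter, which high counts in these libraries alone can meet. Some are contigs of 1 cluster that share reads, so the intervals over these features may be too narrow. Feature length as the whole cause is argued against by the value after removal of the length trend, 4.31 [3.83, 5.11], with 14 against 15 of the 23 called higher. Depth is argued against in leaf, where the uncut and cut libraries hold 941190 and 976805 nuclear counts and the median ratio is 4.38 [3.65, 4.9]. In rhizome the ratio is 0.97 [0.37, 2.57], held down by the floor of 3 counts, but depth is argued against there as well, since it leaves shares as they are: these features hold 33.0 times [24.1, 46.4] the share of nuclear counts in cut that they hold in uncut rhizome, and at least 28.5 times with any 1 of them left out. Carry-over of genomic DNA, in which these families have many copies, stays open, and so may a response of the explants to cutting, which was not tested apart from it.

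The features called higher at 4 days are long, with a median of 2270.5 bases. Carry-over of genomic DNA may account for part of them. The least expressed 44 organelle features have a median log2 ratio of 3.98 [3.66, 4.32] in leaf and 1.68 [1.45, 2.12] in rhizome. They were ranked by counts per base among those with at least 50 counts over the 8 libraries. High counts in the cut libraries at 4 days alone can meet this, so these ratios do not decide it. All chloroplast- or mitochondrion-encoded features with at least 50 counts in a pair had medians of 0.45 in leaf and 0.24 in rhizome. By the size rule 20 were higher and 6 lower in leaf, and 15 and 14 in rhizome. Carry-over at a constant rate per kilobase is not decided by the subtraction, which left 44 of the 542 called higher. Its rate was read from long features of the same libraries, and it moved the median log2 change of all features from 0.13 to -1.18. Feature length bias of another origin could account for part too, since 223 stayed called higher with the length offset. The median log2 change of the 542 went from 4.07 [3.85, 4.29] to 2.77 [2.48, 3.15], so that calls ended as the changes shrank. The tests do not separate it from carry-over, and a response to cutting stays open, untested.

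More features were higher than lower at a month, 89.1% of those called. The low depth of uncut rhizome at 4 days is argued against as the whole cause, since 79.6% were higher without that pair. Feature length bias is argued against as the whole cause, since 75.2% [66, 83] of the calls were higher even at 2000 to 4000 bases, where the median log2 change of all features is -0.32. It may account for part, since the percent of calls higher fell with length: 96.5% [87.9, 99.6] under 500 bases, 91.3% up to 1000, 90.3% up to 2000, the 75.2% above, and 3 of 6 calls at 4000 bases and over. This is not separated from carry-over into the cut libraries at 4 days. Such carry-over is argued against as the whole cause of the excess by a run chosen after the result was seen. In the 4 uncut libraries alone 82.1% of calls were higher (349 higher and 76 lower). That run still holds uncut rhizome at 4 days, and the run without that pair still holds the cut libraries at 4 days. Low depth and carry-over acting together are therefore not argued against. The length offset does not decide on feature length, since it left 63.7% higher but moved the median log2 change of all features from 0.02 to -0.52. For the late embryogenesis and dehydrin features the median with the offset, 5.48 [-0.87, 7], against 6.25 [0.07, 7.68] before, does not decide, since its interval reaches 0. Length as the whole cause is argued against by the 66.7% [38.4, 88.2] of them still called higher with the offset, against 5.95% of all features. For these a change of the explants with time stays open as a hypothesis, untested.

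Since each test is over matched pairs, only the 8 splits of the libraries that part all 4 pairs compare like with like, too few for a share under 0.05. The real split by tissue gave 1051 features and the highest of the other 7 gave 0, so 1 of 8 gave as many. For time the values are 1023 and 0, again 1 of 8. For cutting 2 of 8 splits gave at least the 1 real feature, the highest other giving 87. Of all 32 splits that could be fitted, 4 gave as many as cutting. The highest of these, with 491, sets the cut libraries at 4 days and the rhizome libraries at a month against the other 4, a grouping that crosses tissue, cutting and time.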

How the results depend on the processing

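All tests with the length offset, the subtraction, summed contigs, the removal of ribosomal RNA and organelle features or the 4 uncut libraries alone, and all alternatives within a tissue or a time point, were chosen after the result was seen. Unless stated, the cause was not tested. The tissue count of 1051 became 1608 with no filter, 2582 and 2270 on FPKM with 1 and 0.1 added, 637 with the subtraction and 444 to 992 leaving out a pair. The time count of 1023 became 499 with the subtraction, 425 without the cut libraries (fewer samples) and 589 to 984 leaving out a pair. The single cutting call became 77 by DESeq2, 113 with no filter, 3 and 4 on FPKM, 12 with the length offset, 3 with summed contigs, 0 to 274 leaving out a pair, and 0 in the additive model, with the subtraction and without ribosomal RNA and organelle features. Within leaf, 0 became 8 with the length offset, 3 with the subtraction and 0 to 40 leaving out a pair. Within rhizome, 3 became 14 by DESeq2, 0 with the stricter filter, 14 with the length offset, 35 with the subtraction and 0 to 30 leaving out a pair. The tissue difference of 0 became 1 by DESeq2, 3 with the length offset, 2 with the subtraction and 0 to 4 leaving out a pair.

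At 4 days, 816 became 428 by DESeq2, 300 with the stricter filter, 440 with the length offset, 176 with the subtraction and 169 to 405 leaving out a pair. At a month, 34 became 12 by DESeq2, 0 with the stricter filter, 19 with the length offset, 0 with the subtraction and 5 to 23 leaving out a pair. The time difference of 229 became 102, 18, 114, 0 and 9 to 91 in the same order. In single pairs (leaf then rhizome at 4 days, leaf then rhizome at a month), a minimum of 10 counts gave 2110, 844, 511 and 529, one of 200 gave 173, 151, 49 and 23, and a fold of 2 gave 1997, 1659, 1012 and 366. FPKM gave 2215 in rhizome at 4 days and 960 in leaf at a month.

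The ratio correlation of 0.587 at 4 days became 0.477 with 10 counts; leaf at 4 days with rhizome at a month went from 0.165 to 0.101 with 10 and 0.243 with 200. Rhizome at 4 days with rhizome at a month went from 0.099 to 0.024 and 0.201, and with leaf at a month from 0.036 to -0.003 and -0.029, a change of sign. Lists passing for tissue, cutting and time (11, 5 and 16) were 0 each with an estimated correlation, 3, 0 and 6 by fry, 28, 0 and 27 by its mixed test, and 7 to 11, 1 to 11 and 11 to 15 leaving out a pair. Of the named features at 4 days, 2 changed sign with the length offset: sucrose synthase (CL1148.Contig2) at -0.07 and ribosomal protein S4 (CL308.Contig3) at -0.08. Over all comparisons the length offset left 218 named features past the threshold in the same direction and 45 short of it. The subtraction left 160 and 100, the DESeq2 test 237 and 25. These losses were uneven. The length offset left 36 and 30 at 4 days and 6 and 4 at a month, against 88 and 5 for tissue and 87 and 6 for time. The subtraction left 25 and 39 at 4 days, 70 and 22 for tissue and 65 and 28 for time, and all 10 named at a month fell short. The median log2 change of all features moved from -0.14 for tissue to -0.73 and -1.30 on FPKM and 0.23 with the length offset, from 0.02 for time to -0.52 with the length offset and 0.63 with the subtraction, and from 0.13 at 4 days to -1.18 with the subtraction. The depth of uncut rhizome at 4 days, with 120332 nuclear counts or 68710 without Unigene19161, limits the rhizome pair at that time to its most abundant features.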

Other observations

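The tests with the length offset, the lists within a time point, the ratios without 1 library and the scalings of list medians were chosen after the result was seen. Between the tissues, aquaporins had 5 of 25 members lower in rhizome (9 lower and 1 higher adjusted over the list alone; median log2 -1.46, adjusted p = 0.00991; adjusted p = 0.758 with an estimated correlation) and NAC factors 8 of 31 (13 lower and 1 higher adjusted over the list alone; median -1.12, 0.00488; adjusted p = 0.758 with an estimated correlation). Among them, the tonoplast aquaporin TIP1 (CL1044.Contig1) fell by 2.02 ± 0.42 and NAC29 (Unigene4329) by 3.15 ± 0.71, in all 4 pairs. Without the uncut 4-day pair neither passed (-1.94 and -3.36), and NAC29 did not without the uncut month pair (-2.06), its value being -3.94 without the cut month pair. The clock gene LHY (CL650.Contig1) fell by 2.48 ± 0.44 in rhizome and the granule-bound starch synthase GBSS2 (CL88.Contig2) by 2.37 ± 0.49. The protein GOS9 (Unigene11046; jacalin-related lectin 3 by SwissProt) had 134 counts in rhizome and 0 in leaf, at least 102-fold higher, or at least 59.6-fold without uncut leaf at a month, and did not reach the count filter without either 4-day pair.

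Further named features changed between 4 days and a month. Trehalose-phosphate phosphatase F (CL458.Contig1) rose by 4.51 ± 0.77 and the sugar transporter MST4 (Unigene9259) by 4.48 ± 0.72, each in 4 of 4 pairs. Without the cut leaf pair they rose by 5.17 and 3.79, the first by 3.81 without the uncut and the other by 5.30 without the cut rhizome pair. The clock gene GIGANTEA (CL1023.Contig2) rose by 1.96 ± 0.46 (adjusted p = 0.0184), but with 1 pair left out it passed only where that was the uncut rhizome pair (1.87). The linker histone H1-I (Unigene4969) fell by 3.83 ± 0.91, also in 4 of 4 pairs, by 4.71 without the cut and 2.88 without the uncut leaf pair, and the call ended without the uncut rhizome pair (-3.63).

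In leaf at a month, cut explants lay above uncut ones for jasmonate genes (median log2 0.91) and for late embryogenesis and dehydrins (1.36), each at percentile 100 of random lists. By the size rule 3 jasmonate genes were higher and 2 lower. Heat shock proteins (0.68), histones (0.74) and ribosomal proteins (0.25) also lay at percentile 100. Storage proteins and lectins lay at -0.61, below all but 0.1% of random lists and 0.2% of those matched on length. In rhizome at a month the jasmonate, dehydrin and storage lists lay at 0.08 (percentile 86.9), 0.92 (99.1) and 0.15 (67), the last with the opposite sign.

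CL343.Contig1, named a 36.4 kDa proline-rich protein by SwissProt, matches the 18S to 28S ribosomal repeat by nucleotide and was counted with ribosomal RNA. The 10th percentile of counts per kilobase over nuclear features of at least 2000 bases is 17.7 in cut leaf and 14 in cut rhizome at 4 days. Over 6209 features, the log2 values of uncut and cut libraries correlate with r = 0.863 in leaf and 0.833 in rhizome at a month, and with 0.655 and 0.564 at 4 days, where cut leaf and cut rhizome reach 0.805; features are not independent replicates.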
